A study of Mus musculus with 12 samples.

How the data were processed

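RNA from day 1 decidual uteri of ovariectomized mice was hybridised to 12 single-colour Affymetrix mouse expression arrays, in 4 groups of 3, with 2 mice pooled for each array, per the labels' protocols. Groups were taken from the genotype in the labels (EGFR f/f, EGFR d/d, Wnt4 f/f, Wnt4 d/d), and replicates were numbered in an order that carries no pairing. RNA was amplified with a 3′ in vitro transcription kit and biotin-labelled, per the labels' protocols. The deposited table held log2 values between 2.36 and 14.7. The sorted values of any 2 arrays differed by at most 0.17, so the arrays had been brought to a common distribution by the authors. The software and method for summarising and normalizing are not given in the sources used here. Such normalization removes any change shared by all genes. The table held 0 columns of other series.

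Values were used as deposited, with no further normalization, floor or intensity filter. Within groups, arrays correlated between 0.9956 and 0.9974, and none was a copy of another. The platform annotation listed 34958 probe sets with 1 gene, 932 with several and 9211 with none. Symbols were updated by Entrez ID for 34754 probe sets through a RefSeq gene table (GRCm38.p6), which served for names and for the order of neighbouring genes alone, and no coordinates are given. Each of 18194 genes was represented by its 1-gene probe set with the highest mean over all arrays. Probe sets can share signal between close paralogs.

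A group-means model over all 12 arrays was fitted with limma 3.58.1 (with statmod 1.5.0, in R 4.3.3), which left 8 residual degrees of freedom. Contrasts were d/d minus f/f in each experiment and the EGFR effect minus the Wnt4 effect, with Benjamini-Hochberg adjusted p under 0.05. Errors after ± are limma's moderated standard errors of the log2 fold change, with 3 arrays per group. Their variance is pooled over all 12 arrays, so a gene has the same error in both comparisons. The experiments had separate controls. The labels name no batch, and experiment and mouse line coincide. Of 830 members of 36 gene lists (20 pathway lists and 16 cell type lists), 772 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 36 lists of a comparison. A count adjusted over the list alone repeats the adjustment within the list. Correlations between the effects were tested over the 100 splits of the arrays within both experiments.

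On simulated arrays with the spread of the real genes, 80% of genes changed by 0.5 and 97% of genes changed by 1 on the log2 scale were recovered in the EGFR comparison of 18194 genes, and 9 of 17994 unchanged genes were called. For the difference of effects 7 of 17994 unchanged genes were called, and for the Wnt4 comparison 0 of 18194. In the simulation of camera, the shifted list was found and 0 of 35 other lists were called. Genes were drawn independently there, whereas the estimated correlation reached 0.66 in the real G2 and mitosis list. The simulation therefore does not check false calls of lists whose genes move together.

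The comparisons, gene lists, alternatives and the rule for named genes were set before the data were examined. The gene families, the comparisons of control groups, the exchange of the Wnt4 labels and several tests of explanations were chosen after values had been seen. The rule took Egfr, Wnt4, Pgr and Bmp2 always. Per comparison it took the 8 largest rises and falls among genes past the threshold whose d/d arrays all lay beyond the f/f arrays and whose higher group mean reached the median gene, passing over predicted genes and clones. Up to 4 members of each list with the largest change past the threshold, 5 genes per direction for the difference and 6 per direction for shared genes were added. Of the list members so taken, those printed were mostly the leading members of lists past camera. The choice among them was made after values were seen, and in an earlier choice some were passed over because their calls were lost when an array was left out. Some, such as Hand2, were taken through another list that also holds them. The basal keratinocyte and clock genes named only in the closing section stand outside the rule.

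Alternatives were quantile normalization over all arrays or within each experiment, median centring, leaving out genes under the 30th percentile of mean signal, a trended and robust variance, array weights, separate fits of the experiments, the mean of all probe sets of a gene, plain probe sets alone, a fold of at least 1.5, an estimated correlation and leaving out each array. The labels do not give the floxed exons, so no probe set could be placed inside or outside them. Probe sets with several genes were left out, and those with none were tested apart.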

Results

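Gene expression was measured in mouse uteri at decidual day 1, the early phase of decidualization, in which the stromal cells of the endometrium turn into the decidua that supports the embryo. Ovariectomized mice received the artificial decidualization procedure. There were 4 groups of 3 arrays, and each array held a pool of RNA from 2 mice, so p-values measure the spread between such pools. EGFR f/f and EGFR d/d were the control and conditional knockout of Egfr, the receptor for epidermal growth factor. Wnt4 f/f and Wnt4 d/d were the control and conditional knockout of Wnt4, a secreted Wnt ligand. Cre recombinase driven by the progesterone receptor gene was used to delete the floxed alleles. On the array, probe sets naming a single gene gave values for 18194 genes. Array data have no read depth, so the 3 arrays per group limit the precision. The questions were which genes depended on EGFR, which depended on Wnt4, and how far the effects of both knockouts ran together.

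The targeted genes came first. Egfr was lower in EGFR d/d by a log2 fold change of -1.57 ± 0.06 (SE, 3 arrays per group; limma adjusted p = 1.85e-07), a 2.98-fold difference, from a mean log2 signal of 10.13 to 8.55. In the arrays labelled Wnt4 d/d the Egfr change was -0.11 ± 0.06 (limma adjusted p = 0.241), or -0.19 (adjusted p = 0.023) in the mean of all its probe sets. Wnt4 fell in EGFR d/d by a log2 fold change of -1.68 ± 0.12 (limma adjusted p = 1.92e-06), but it was not lower in the arrays labelled Wnt4 d/d, where the change was 0.12 ± 0.12 (limma adjusted p = 0.534). Its mean log2 signal was 9.13 in EGFR f/f, 7.45 in EGFR d/d, 7.48 in Wnt4 f/f and 7.6 in Wnt4 d/d. The other Wnt4 probe set gave a change of 0.16 in the arrays labelled Wnt4 d/d (limma adjusted p = 0.156). The labels do not state which exons were floxed, and probe sets outside the deleted part would not check the genotype, so every direction given below for this group rests on its label. Pgr, the progesterone receptor gene that carries the Cre, had changes of -0.01 ± 0.06 in EGFR d/d and -0.07 ± 0.06 in Wnt4 d/d on its brightest probe set. Its other probe sets went opposite ways, with -0.51 and -0.91 in EGFR d/d and Wnt4 d/d for the first and 0.72 and 0.56 for the other.

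**Figure D1:**
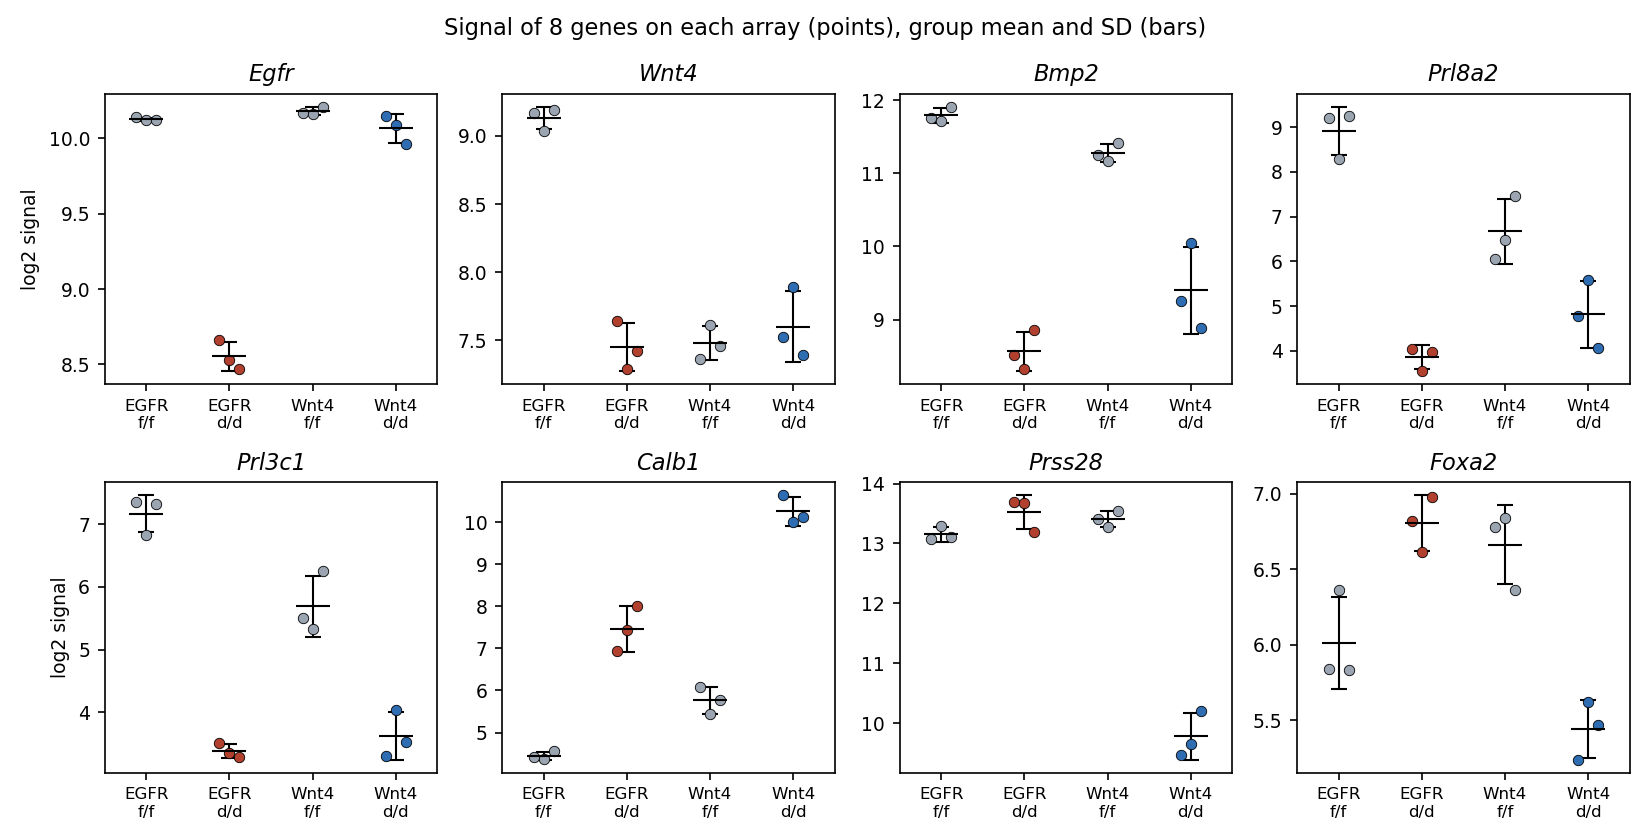
Log2 signal (vertical axis) of 8 genes on each of the 12 arrays, grouped by genotype label (horizontal axis). Points are arrays, long bars are group means and whiskers are the SD of 3 arrays. Egfr and Wnt4 were both lower in EGFR d/d, Wnt4 was near 7.5 in the other groups except EGFR f/f, and Prss28 and Foxa2 were lower in the arrays labelled Wnt4 d/d alone.

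Prl8a2, Prl3c1, Bmp2 and Ptgs2, genes of the decidual response, fell in EGFR d/d uteri. Prl8a2, the decidual prolactin-related protein, had a log2 fold change of -5.05 ± 0.41 (limma adjusted p = 2.91e-06). Prl3c1, a related prolactin family member, fell by 3.79 ± 0.24. In EGFR d/d their mean log2 signals of 3.86 and 3.38 lay under the array medians, the lowest of which was 5.96. The background of these probe sets is not given, so the true falls can be larger. Bmp2, a bone morphogenetic protein needed for decidualization, fell by 3.23 ± 0.23, a 9.36-fold fall (limma adjusted p = 1.46e-06). Ptgs2, the inducible enzyme of prostaglandin synthesis, fell by 2.89 ± 0.42. The largest other falls were those of Aoc1, the histamine-degrading diamine oxidase (-4.36 ± 0.31), Plekhg4, an exchange factor for Rho proteins (-3.91 ± 0.26), and Serpinb9b, a protease inhibitor (-3.65 ± 0.16). Next came Sfrp5, a secreted Wnt antagonist (-3.59 ± 0.27), Cyp11a1, the enzyme that starts steroid synthesis from cholesterol (-3.58 ± 0.29), and Aass, an enzyme of lysine breakdown (-3.39 ± 0.31). Rises and falls were ranked only among genes that met the naming rule's conditions on threshold, separation and signal. The largest such rises were those of Calb1, a calcium-binding protein (3 ± 0.24), and Mmp7, the epithelial metalloproteinase matrilysin (2.58 ± 0.19). Inmt, an amine methyltransferase (2.57 ± 0.14), and Car3, a carbonic anhydrase (2.44 ± 0.54), followed. Next came Dbp, a clock-controlled transcription factor (2.42 ± 0.14), Csrnp3 (2.39 ± 0.11), F5, coagulation factor V (2.37 ± 0.2), and Chodl, the membrane lectin chondrolectin (2.35 ± 0.16). The 8 largest rises and falls were taken only among genes whose 3 d/d arrays all lay beyond all 3 f/f arrays. Their separation was thus fixed by the choice, and their limma adjusted p was at most 0.00285. Of the 18194 genes, 7740 passed a limma adjusted p of 0.05, with 4200 higher and 3540 lower in EGFR d/d, and 549 of them changed at least 2-fold. The balance turned under median centring (3737 higher and 3951 lower). The groups did not overlap for 51.9% of genes, where chance gives 10%.

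Cell cycle genes fell together in EGFR d/d. Of the 40 measured genes of G1/S and DNA replication, 36 fell and 0 rose, and the same numbers held adjusted over the list alone. Examples were Rrm2, the ribonucleotide reductase subunit (-2.23 ± 0.17), Cdc6, which loads the replicative helicase (-1.31 ± 0.1), and Ccne2, cyclin E2 (-1.2 ± 0.14). Of the 39 measured genes of G2 and mitosis, 38 fell and 0 rose, with 39 falls adjusted over the list alone, among them the mitotic kinases Aurkb (-1.18 ± 0.09) and Aurka (-1.17 ± 0.11). The median log2 fold changes were -0.64 and -0.77. Both lists shifted down by limma's camera with its preset correlation (adjusted p = 3.6e-17 and 5.79e-19), though not with an estimated correlation (adjusted p = 0.325 and 0.326 with an estimated correlation). Of 41 measured decidualization genes, 21 fell and 11 rose, the same adjusted over the list alone. Hand2, a stromal transcription factor, fell by 1.14 ± 0.09, whereas Dio2, a thyroid hormone deiodinase on the same list, rose by 2.25 ± 0.15. The list shifted down by camera (adjusted p = 0.00555, and adjusted p = 0.325 with an estimated correlation).

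Cholesterol synthesis, unfolded protein response, heat shock, and glycolysis and hypoxia lists shifted down as well in EGFR d/d by camera with the preset correlation. Of 20 measured cholesterol synthesis genes, 16 fell and 0 rose, and 16 fell adjusted over the list alone. They included Hsd17b7 (-1.2 ± 0.13) and Cyp51, lanosterol demethylase (-1.05 ± 0.1), and the list median was -0.53 (camera adjusted p = 5.64e-07, and adjusted p = 0.325 with an estimated correlation). In the unfolded protein response list 15 of 22 genes fell and 3 rose, and 17 and 3 did adjusted over the list alone. Asns, asparagine synthetase, fell by 0.84 ± 0.13 and Chac1, a glutathione-degrading enzyme, by 0.74 ± 0.1 (camera adjusted p = 0.000371, and adjusted p = 0.326 with an estimated correlation). Of 14 heat shock genes, 9 fell and 1 rose, and 9 and 3 did adjusted over the list alone, with the chaperones Hsph1 at -1.03 ± 0.1 and Hspd1 at -0.81 ± 0.06 (camera adjusted p = 0.00285, and adjusted p = 0.457 with an estimated correlation). Of 31 genes of glycolysis and hypoxia, 16 fell and 7 rose, the same adjusted over the list alone, with hexokinase Hk2 at -1.92 ± 0.19 and the collagen prolyl hydroxylase subunit P4ha2 at -1.24 ± 0.11 (camera adjusted p = 0.0466, and adjusted p = 0.543 with an estimated correlation). This last call was lost without EGFR d/d replicate 1 (adjusted p = 0.0568) or replicate 2 (0.0887), and without EGFR f/f replicate 1 (0.0555) or replicate 3 (0.0632).

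Markers of several other uterine cell types rose in EGFR d/d. Of 21 epithelial markers, 19 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 1.13. Ehf, an epithelial transcription factor, rose by 1.65 ± 0.14, the secreted protein Wfdc2 by 1.63 ± 0.11 and the tight junction protein Cldn7 by 1.5 ± 0.12 (camera adjusted p = 9.69e-11, and adjusted p = 0.286 with an estimated correlation). Of 12 glandular markers, 7 rose and 0 fell, also adjusted over the list alone, among them Calb1, Wfdc3 (0.82 ± 0.12) and the gland transcription factors Sox9 (0.82 ± 0.13) and Foxa2 (0.79 ± 0.17) (camera adjusted p = 0.00384, and adjusted p = 0.326 with an estimated correlation). The calls of members Prss29 and Spink1 were lost in 4 and 3 of the 12 fits without 1 array (limma adjusted p up to 0.104 and 0.0893). Prss28 did not pass, but did in some alternatives, such as array weights (0.43, limma adjusted p = 0.041). The endothelial list had 16 of 18 genes up and 0 down, also adjusted over the list alone, including von Willebrand factor Vwf (1.38 ± 0.16) and the angiopoietin receptor Tek (1.04 ± 0.08). Its member Cdh5, which did not pass, was -0.25 in the mean of all its probe sets (limma adjusted p = 0.00986). The smooth muscle list had 13 of 17 up and 0 down, also adjusted over the list alone, including Pcp4 (1.03 ± 0.08), Synpo2 (0.81 ± 0.07), which turned to -0.3 in the mean of all its probe sets, and smoothelin, Smtn (0.79 ± 0.07). The pericyte list had 7 of 8 up, also adjusted over the list alone, including the growth factor receptor Pdgfrb (0.86 ± 0.06) and the potassium channel subunit Kcnj8 (0.86 ± 0.06). The macrophage and dendritic list had 15 of 20 up and 0 down, 16 adjusted over the list alone, including the antigen-presenting molecule H2-Aa (1 ± 0.09) and Mpeg1 (0.95 ± 0.12). Camera adjusted p was 1.18e-06, 3.54e-05, 3.54e-05 and 4.21e-05 for the endothelial, smooth muscle, pericyte and macrophage lists, against adjusted p = 0.142, 0.326, 0.106 and 0.444 with an estimated correlation. Beside them, 7 of 14 stromal fibroblast markers rose and 2 fell, 8 and 2 adjusted over the list alone, with a median of 0.21 that did not pass camera (adjusted p = 0.107).

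Interferon response genes rose in EGFR d/d, 21 of 27 with 0 falls, or 22 adjusted over the list alone. Ifit3, an antiviral effector, rose by 1.5 ± 0.21, and the guanylate-binding proteins Gbp2 and Gbp3 rose by 1.29 ± 0.12 and 1.26 ± 0.15 (camera adjusted p = 1.68e-06, and adjusted p = 0.458 with an estimated correlation). Of 36 extracellular matrix genes, 15 rose and 3 fell, also adjusted over the list alone, with the metalloproteinase Mmp11 at 1.36 ± 0.08 and the basement membrane collagen Col18a1 at 0.92 ± 0.08 (camera adjusted p = 0.00829, and adjusted p = 0.479 with an estimated correlation). Of 31 estrogen response genes, 13 rose and 3 fell, also adjusted over the list alone, with the water channel Aqp8 at 1.62 ± 0.29 and the deiminase Padi1 at 1.39 ± 0.19 (camera adjusted p = 0.0488, and adjusted p = 0.479 with an estimated correlation). The estrogen call was lost without any of EGFR d/d replicates 1 and 3 (adjusted p = 0.0825 and 0.0534), EGFR f/f replicate 1 (0.0667), Wnt4 d/d replicates 2 and 3 (0.0582 and 0.0503) and Wnt4 f/f replicates 1 and 2 (0.0568 and 0.0504). In all, 16 of the 36 lists shifted by camera with the preset correlation, 9 up and 7 down, and 0 did with an estimated correlation, where the lowest adjusted p was 0.106.

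The other lists did not pass camera with the preset correlation in EGFR d/d. Of 18 EGFR ligand and receptor genes, 5 rose and 3 fell, among them Egfr itself, its ligand Hbegf (-0.94 ± 0.08) and the related receptor Erbb3 (0.85 ± 0.09). Of 29 feedback and early genes of ERK signalling, 8 rose and 7 fell, or 9 and 7 adjusted over the list alone, with the transcription factor Fosl1 at -1.68 ± 0.23 and Ier3 at 0.94 ± 0.12. Of 26 targets of Wnt and beta-catenin signalling, 10 rose and 5 fell, with the Wnt-inactivating enzyme Notum at -1.87 ± 0.13 and the pseudoreceptor Bambi at -1.26 ± 0.07, and of 37 Wnt ligands and receptors, 11 rose and 8 fell. Camera adjusted p was 0.587, 0.749, 0.59 and 0.823 for these lists. Progesterone response had 15 rises and 8 falls among 34 genes (adjusted p = 0.28), BMP and TGF-beta signalling 12 and 11 among 34 (0.515), cyclin-dependent kinase inhibitors and senescence 6 and 6 among 20 (0.619), LIF and STAT3 signalling 8 and 5 among 20 (0.57), the retinoid pathway 4 and 5 among 17 (0.59) and angiogenesis 13 and 9 among 27 (0.588). Of the cell type lists, adipocyte markers had 6 rises among 13 (0.0764), mesothelial markers 6 rises and 1 fall among 10 (0.0764), neutrophil markers 1 and 2 among 12 (0.823), natural killer and T cell markers 2 and 0 among 20 (0.619), B and plasma cell markers 2 and 0 among 7 (0.57), and eosinophil and mast cell markers 2 and 0 among 10 (0.258). Erythroid markers had 0 calls among 7 (0.823), ciliated, oviduct and ovary markers 3 rises and 1 fall among 11 (0.823) and nerve and glia markers 3 and 1 among 9 (0.59). Within ciliated, oviduct and ovary markers the fall was that of Cyp11a1, which decidual cells also express.

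The largest changes in the arrays labelled Wnt4 d/d included falls of Prss28, Prss29 and Spink1 and rises of Calb1, Serpina1c and Ltf. Prss28 and Prss29, the implantation serine proteinases of the glands, had log2 fold changes of -3.63 ± 0.18 and -3.39 ± 0.17, a 12.4-fold fall for Prss28 (limma adjusted p = 3.07e-07). Spink1, a secreted trypsin inhibitor, fell by 3.18 ± 0.17. The other large falls were those of Tdo2, the tryptophan dioxygenase of decidual cells (-2.82 ± 0.13), Nppa, atrial natriuretic peptide (-2.44 ± 0.1), Tac2, the neurokinin B precursor (-2.42 ± 0.12), Prss12, a serine protease (-2.19 ± 0.1), and Agr2, a disulfide isomerase of mucus-secreting cells (-2.11 ± 0.19). Calb1 rose by 4.49 ± 0.24 (limma adjusted p = 5.84e-07). Serpina1c, an antitrypsin family member, rose by 4.32 ± 0.28, the estrogen-induced iron-binding protein Ltf by 4.12 ± 0.38, and Clca1 by 4.09 ± 0.29. The squamous epithelial protein Sprr2f rose by 3.04 ± 0.41, the basal epithelial keratin Krt15 by 3 ± 0.16, Tmem45b by 2.72 ± 0.18 and the membrane protein Ano4 by 2.69 ± 0.16. These genes were taken only where all 3 d/d arrays lay beyond all 3 f/f arrays, so their separation was fixed by the choice. Their limma adjusted p was at most 0.000343. Prl8a2, Serpina1c and the paired proteinases belong to families of close paralogs, whose probes can share signal. Of the 18194 genes, 4391 passed a limma adjusted p of 0.05, with 2426 higher and 1965 lower, and 248 of them changed at least 2-fold. The balance turned in the mean of all probe sets (1915 higher and 1985 lower).

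Cell cycle genes and part of the decidual genes fell in the arrays labelled Wnt4 d/d too. Bmp2 fell by 1.88 ± 0.23, a 3.67-fold fall (limma adjusted p = 0.00018), and Prl3c1 by 2.07 ± 0.24, while Dio2 rose by 1.98 ± 0.15. Of the 41 decidualization genes, 13 fell and 7 rose, or 14 and 7 adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.344 with an estimated correlation). Of the 40 G1/S genes, 36 fell and 1 rose, or 36 and 2 adjusted over the list alone, with Rrm2 at -1.24 ± 0.17, Ccne2 at -0.73 ± 0.14 and thymidine kinase Tk1 at -0.64 ± 0.08. Of the 39 G2 and mitosis genes, 34 fell and 0 rose, or 36 and 0 adjusted over the list alone, with Aurkb at -0.84 ± 0.09 and Plk1 at -0.75 ± 0.09. The medians were -0.41 and -0.44 (camera adjusted p = 4.22e-16 and 1.01e-18, and adjusted p = 0.344 for both with an estimated correlation). In the unfolded protein response list 14 of 22 genes fell and 0 rose, also adjusted over the list alone, with Creld2 at -0.81 ± 0.1 and Sdf2l1 at -0.71 ± 0.08 (camera adjusted p = 3.02e-07, and adjusted p = 0.344 with an estimated correlation). Of 31 glycolysis and hypoxia genes, 10 fell and 2 rose, or 13 and 3 adjusted over the list alone, with Hk2 at -1.18 ± 0.19 and the glucose transporter Slc2a3 at -0.65 ± 0.1 (camera adjusted p = 0.0173, and adjusted p = 0.64 with an estimated correlation). With plain probe sets alone Slc2a3 was -0.02 (limma adjusted p = 0.942). Of 20 cholesterol synthesis genes, only the regulator Srebf2 passed over all genes, at -0.2 ± 0.06, and 0 passed adjusted over the list alone. That list shifted by camera (median -0.13, adjusted p = 0.0401, and adjusted p = 0.64 with an estimated correlation), but not without Wnt4 d/d replicate 3 (adjusted p = 0.168), Wnt4 f/f replicate 2 (0.0584) or Wnt4 f/f replicate 3 (0.0523). Srebf2 itself missed the threshold in 5 of the 12 fits that each left out 1 array, with -0.15 and a limma adjusted p of 0.138 without Wnt4 d/d replicate 3. It also missed it with array weights (-0.17, adjusted p = 0.0606), in separate fits (-0.2, 0.0948) and in the mean of all probe sets (-0.14, 0.174). Cyp51, at -0.3 with a limma adjusted p of 0.0532, passed with array weights (-0.32, 0.0295), without dim genes (-0.3, 0.0365), in the mean of all probe sets (-0.24, 0.0384) and with a trended, robust variance (-0.3, 0.0253). It also passed without EGFR d/d replicate 3 (0.0335), EGFR f/f replicate 1 (0.045) or Wnt4 d/d replicate 2 (0.0183). Hsd17b7, at -0.33 with 0.0887, passed in the mean of all probe sets (-0.39, 0.025) and without Wnt4 d/d replicate 2 (-0.45, 0.0236).

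Most epithelial markers rose and most glandular markers fell in the arrays labelled Wnt4 d/d. Of 21 epithelial markers, 15 rose and 1 fell, or 17 and 1 adjusted over the list alone. Keratin Krt19 rose by 1.59 ± 0.21, Wfdc2 by 1.4 ± 0.11 and Cldn7 by 1.27 ± 0.12, and the marker that fell was prominin, Prom1 (-1.44 ± 0.15). The median was 0.71 (camera adjusted p = 1.06e-09, and adjusted p = 0.344 with an estimated correlation). Of 12 glandular markers, 7 fell and 2 rose, or 8 and 2 adjusted over the list alone, with a median of -0.82 (camera adjusted p = 0.00138, and adjusted p = 0.344 with an estimated correlation). Foxa2, needed for gland development, fell by 1.22 ± 0.17 and Sox9 by 1.71 ± 0.13, and the members that rose were Calb1 and Ltf, which estrogen also regulates in the uterine epithelium. Calb1 was among the glandular markers that rose in EGFR d/d too. The estrogen response list did not pass camera in the arrays labelled Wnt4 d/d (adjusted p = 0.28). Resampling the glandular genes gave a 95% interval of their median of -2.44 to 0.12, which includes 0. Interferon response genes rose, 16 of 27 with 0 falls, or 21 and 1 adjusted over the list alone, with Oasl2 at 1.4 ± 0.19 and Rtp4 at 1.27 ± 0.16 (camera adjusted p = 8.67e-08, and adjusted p = 0.541 with an estimated correlation). Of 8 pericyte markers, 5 rose and 0 fell, or 6 and 1 adjusted over the list alone, with Abcc9 and Notch3 both at 0.58 (camera adjusted p = 0.000502, and adjusted p = 0.215 with an estimated correlation). Of 20 macrophage and dendritic markers, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone, with Cd14 at 0.79 ± 0.19 and Mpeg1 at 0.66 ± 0.12 (camera adjusted p = 0.00595, and adjusted p = 0.64 with an estimated correlation).

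The endothelial and lymphoid lists shifted by camera in the arrays labelled Wnt4 d/d with few members past the threshold. Of 18 endothelial markers, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with the transcription factor Sox17 at 0.56 ± 0.08, Tek at 0.46 ± 0.08 and the junction protein Cdh5 at -0.44 ± 0.07 (camera adjusted p = 0.0401, and adjusted p = 0.541 with an estimated correlation). The endothelial call was lost without Wnt4 d/d replicate 1 (adjusted p = 0.0526) or Wnt4 f/f replicate 1 (0.0788). Of 20 natural killer and T cell markers, only Eomes (0.49 ± 0.14) and Il2rb (0.25 ± 0.08) passed, and 0 passed adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.541 with an estimated correlation). The lymphoid call was lost without Wnt4 d/d replicate 1 (adjusted p = 0.0522), Wnt4 d/d replicate 3 (0.0908) or Wnt4 f/f replicate 1 (0.0519). Eomes missed the threshold in 3 of the 12 fits without 1 array, with 0.41 and a limma adjusted p of 0.0867 without Wnt4 f/f replicate 2, and Il2rb in 5, with 0.2 and 0.127 without Wnt4 d/d replicate 3. In separate fits and in the mean of all probe sets, Eomes (limma adjusted p = 0.0734 and 0.0514) and Il2rb (0.0759 and 0.0976) missed it too, as did Il2rb with a trended, robust variance (0.0501). In all, 13 of the 36 lists shifted by camera with the preset correlation, 6 up and 7 down, and 0 did with an estimated correlation, where the lowest adjusted p was 0.215. Of 17 smooth muscle markers, 5 rose and 2 fell, and of 14 stromal fibroblast markers, 5 rose and 2 fell, and neither list passed camera (adjusted p = 0.28 and 0.179). Nor did extracellular matrix or heat shock genes, with 15 rises and 7 falls among 36 and 2 rises and 7 falls among 14 (adjusted p = 0.0558 for both). Targets of Wnt and beta-catenin signalling had 5 rises and 6 falls among 26 (camera adjusted p = 0.939). Wnt ligands and receptors had 9 and 5 among 37 (0.92). Progesterone response had 9 rises and 8 falls among 34 (0.92), and estrogen response 10 and 5 among 31 (0.28). The remaining lists did not pass either, with camera adjusted p from 0.0773 to 0.961.

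**Figure D2:**
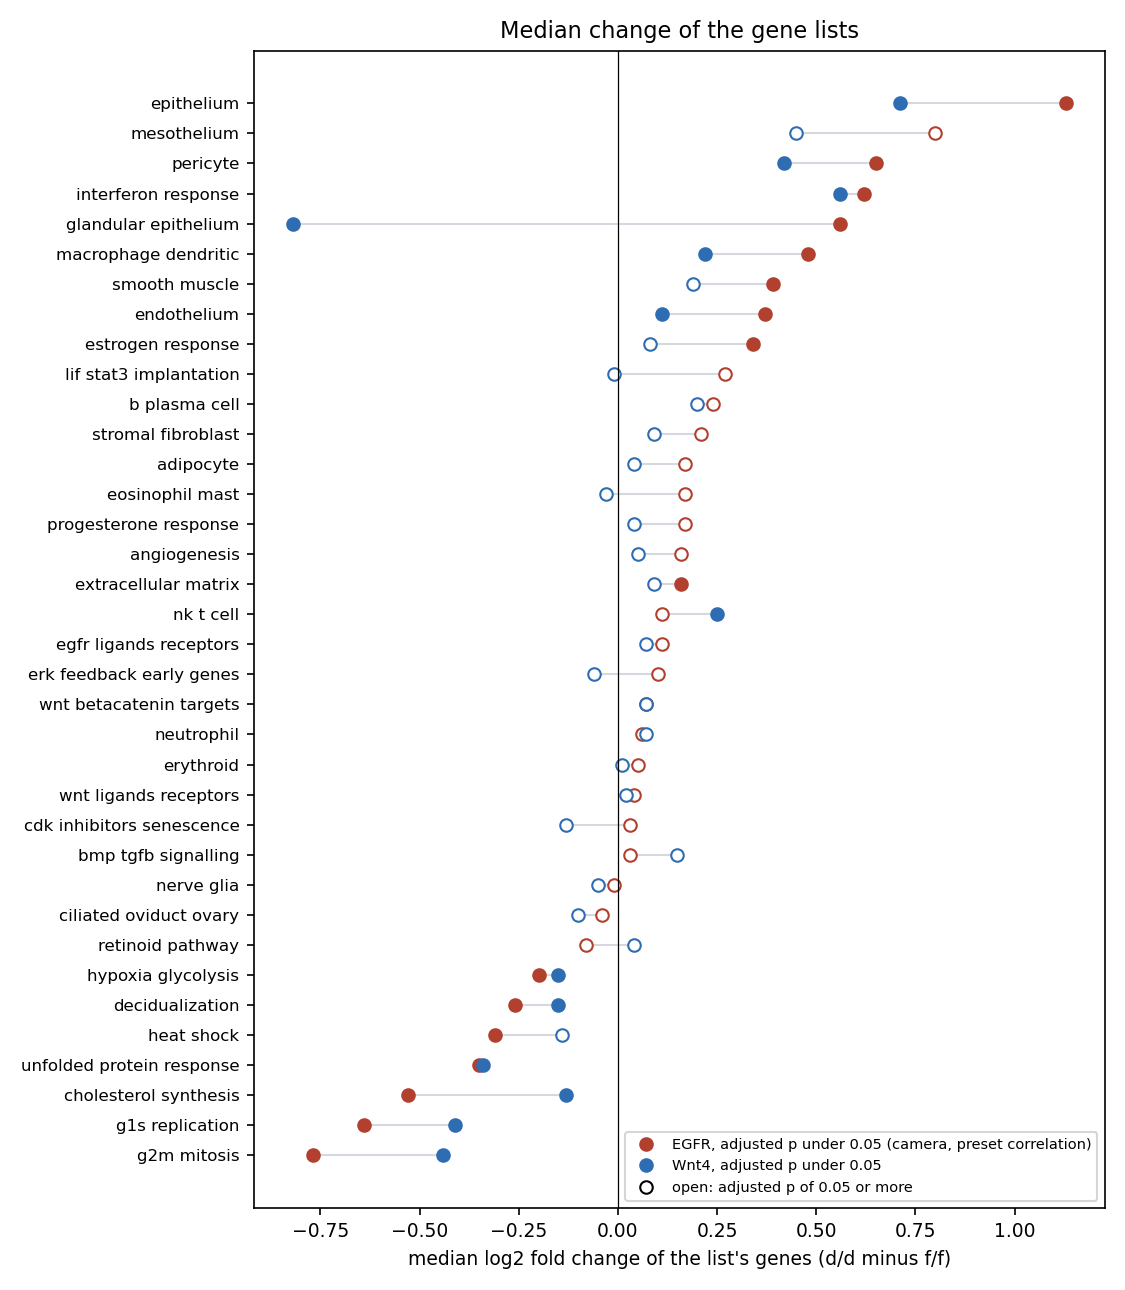
Median log2 fold change, d/d minus f/f (horizontal axis), of the measured genes of each of 36 gene lists (vertical axis), in red for EGFR and in blue for the arrays labelled Wnt4. Filled points passed camera with the preset correlation at an adjusted p of 0.05 and open points did not; the glandular list lay at 0.56 and -0.82.

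Most of the changes in the arrays labelled Wnt4 d/d had the same direction in EGFR d/d, and less of those in EGFR d/d were shared. The shared rises were led by Calb1 (3 and 4.49 in EGFR d/d and Wnt4 d/d), Ano4 (2.36 and 2.69), Dleu7 (2.31 and 2.43), Dio2 (2.25 and 1.98), Serpina1c (1.79 and 4.32) and P2ry14, a receptor for sugar nucleotides (2.03 and 1.72). The shared falls were led by Tdo2 (-2.81 and -2.82), Prkg2, a cGMP-dependent kinase (-3.04 and -2.09), Prl3c1 (-3.79 and -2.07), Bmp2 (-3.23 and -1.88), Map7d2, a microtubule-binding protein (-2.25 and -1.86), and Prl8a2 (-5.05 and -1.85). Of the genes past limma's adjusted threshold in both comparisons, 3550 changed the same way, 1984 higher and 1566 lower, where independent lists would share 942. They made up 80.8% of the Wnt4 calls and 45.9% of the EGFR calls. Only 109 changed opposite ways, where independent lists would share 926, and 96 of them were higher in EGFR d/d and lower in the arrays labelled Wnt4 d/d. The comparisons shared no control arrays. Across genes, the log2 fold changes of the comparisons correlated with a Pearson r of 0.67 and a Spearman rho of 0.69, over genes that are not independent replicates. If the Wnt4 labels were exchanged, 109 genes would have changed the same way and 3550 opposite ways, with an r of -0.67, so the shared direction rests on those labels. The exact permutation p over the 100 splits of the arrays was 0.01 for each (two-sided), the smallest they can give, with a highest other r of 0.66 and rho of 0.6. The covariance was 0.084 against a highest other value of 0.047 (exact permutation p = 0.01), and with 2 correlations and 1 covariance as the family, the adjusted values were also 0.01. Of the 3550 genes, 82.1% had the larger change in EGFR d/d, with a median absolute log2 fold change of 0.56 against 0.37. These changes start from different controls. By limma, 4950 genes differed between Wnt4 f/f and EGFR f/f, among them the shared genes Prl8a2 (-2.25) and Prl3c1 (-1.48). How far the larger changes in EGFR d/d come from the controls was not tested. The effects on 502 of the 3550 genes (14.1%) differed by the test of the difference itself.

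**Figure D3:**
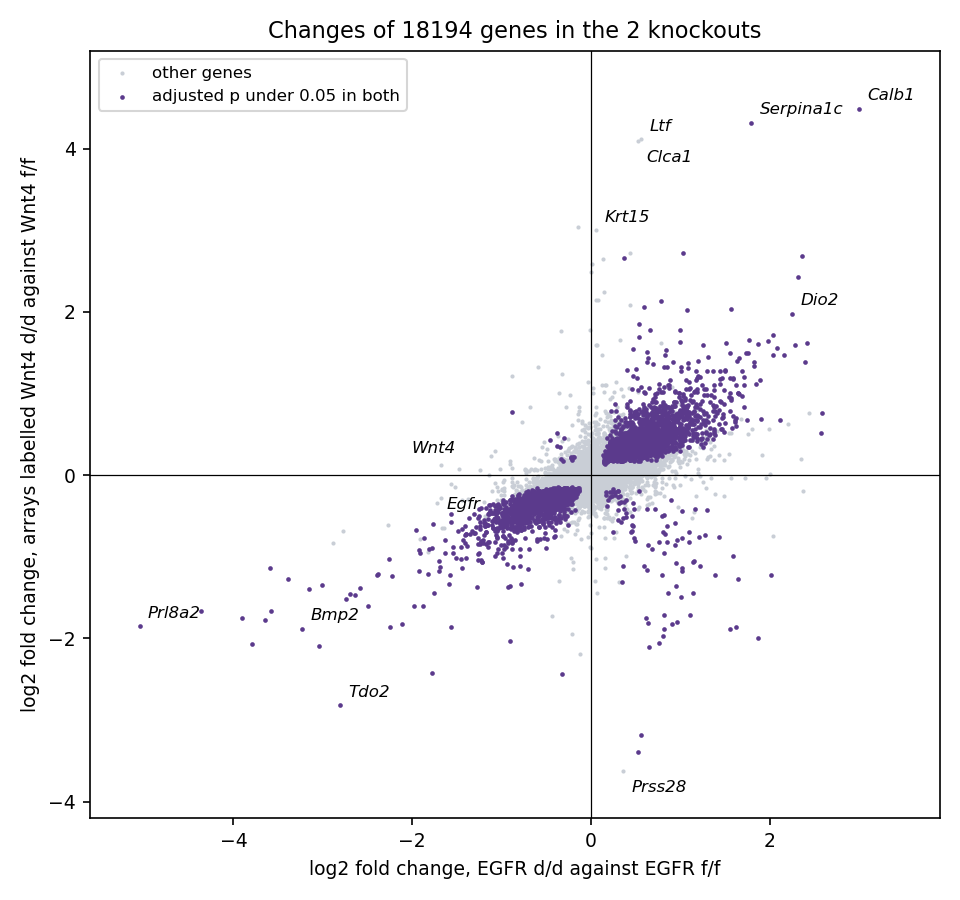
Log2 fold change of each of 18194 genes in EGFR d/d (horizontal axis) and in the arrays labelled Wnt4 d/d (vertical axis), each against its own controls, with genes past an adjusted p of 0.05 in both in purple. Most purple points lay in the quadrants of equal sign (3550 against 109), and Prss28 and Ltf lay far from that trend.

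The effects themselves differed for part of the glandular and endothelial markers. A positive difference here is a higher value of the EGFR effect minus the Wnt4 effect. The largest positive differences were those of Prss28 (3.99 ± 0.25), Prss29 (3.91 ± 0.24), Obp2a, an odorant-binding protein (3.87 ± 0.3), Spink1 (3.74 ± 0.25) and Aqp8 (3.49 ± 0.41), with limma adjusted p of at most 0.00057. Obp2a rose by 1.87 ± 0.21 in EGFR d/d and fell by 2 ± 0.21 in the arrays labelled Wnt4 d/d. The largest negative differences were those of Clca1 (-3.57 ± 0.41), Ltf (-3.56 ± 0.53), Prl8a2 (-3.2 ± 0.58), Sprr2f (-3.19 ± 0.58) and Krt15 (-2.95 ± 0.23), with limma adjusted p of at most 0.00853. The controls of the experiments also differed, and for Prl8a2 Wnt4 f/f lay -2.25 from EGFR f/f while the d/d groups lay 0.95 apart. That gap between controls was larger than the gap between d/d groups for 598 of the 1352 genes whose effects differed. Of 12 glandular markers, 7 had a positive and 2 a negative difference, or 8 and 2 adjusted over the list alone, with Sox9 at 2.52 ± 0.19 and Foxa2 at 2.01 ± 0.24 beside the proteinases. The glandular median of 1.3 was the largest of the 36 lists (camera adjusted p = 4.4e-08, and adjusted p = 0.0896 with an estimated correlation). With the Wnt4 labels exchanged it would be -0.22 (camera adjusted p = 0.516), so this too rests on the labels. Of 18 endothelial markers, 8 had a positive difference and 0 a negative one, or 12 and 0 adjusted over the list alone, with Vwf at 1.19 ± 0.23 and the receptor Tie1 at 0.59 ± 0.09 (camera adjusted p = 1.93e-08, and adjusted p = 0.0896 with an estimated correlation). Of 17 smooth muscle markers, 6 had a positive difference, or 10 adjusted over the list alone, with actin Actg2 at 0.56 ± 0.07 and leiomodin Lmod1 at 0.55 ± 0.1 (camera adjusted p = 9.79e-08, and adjusted p = 0.211 with an estimated correlation). Epithelial markers had 7 positive differences and 1 negative among 21, or 10 and 1 adjusted over the list alone, led by Prom1 (2.58 ± 0.21) and Krt19 (-1.54 ± 0.3), and pericyte markers 3 positive among 8, or 4 adjusted over the list alone. Only Csf1r, a receptor of macrophages, passed among 20 macrophage and dendritic markers (0.57 ± 0.11), or 5 adjusted over the list alone. Camera adjusted p was 4.14e-05, 0.000656 and 0.000656 for these 3 lists, against adjusted p = 0.385, 0.0896 and 0.463 with an estimated correlation.

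Cholesterol, cell cycle, heat shock, decidualization and BMP lists lay lower in the EGFR effect than in the Wnt4 effect by camera with the preset correlation, though not with an estimated one. Of 20 cholesterol synthesis genes, 9 had a negative difference and 0 a positive one, or 14 and 0 adjusted over the list alone, with Msmo1 at -0.9 ± 0.22 and Hsd17b7 at -0.87 ± 0.18 (camera adjusted p = 3.47e-08, and adjusted p = 0.211 with an estimated correlation). With plain probe sets alone, Msmo1 was -0.22 (limma adjusted p = 0.478) and Hsd17b7 -0.56 (0.106), and in the mean of all probe sets Hsd17b7 was -0.46 (0.0996). The G1/S and G2 lists had a median difference of -0.28 each, though only 5 of 40 and 2 of 39 genes passed, or 14 and 1 with a negative difference adjusted over the list alone (camera adjusted p = 1.93e-08 for both, and adjusted p = 0.441 and 0.463 with an estimated correlation). Rrm2 (-0.99 ± 0.24) and Cdc6 (-0.83 ± 0.15) led the G1/S list. Of 14 heat shock genes, 4 had a negative difference, also adjusted over the list alone, led by Hsph1 at -0.65 ± 0.14 (camera adjusted p = 0.00265, and adjusted p = 0.441 with an estimated correlation). Of 34 BMP and TGF-beta genes, 8 were negative and 1 positive, or 12 and 3 adjusted over the list alone, led by Bmp2 (-1.35 ± 0.32) and the inhibitory Smad6 (-1.17 ± 0.27) (camera adjusted p = 0.0118, and adjusted p = 0.0898 with an estimated correlation). Of 41 decidualization genes, 7 were negative and 3 positive, or 15 and 5 adjusted over the list alone, led by Prl8a2 and Wnt4 (camera adjusted p = 0.0472, and adjusted p = 0.385 with an estimated correlation). For Wnt4 the controls lay -1.66 apart and the d/d groups 0.15. Of 20 cyclin-dependent kinase inhibitor and senescence genes, 4 were positive and 1 negative, or 6 and 1 adjusted over the list alone, with the growth arrest gene Gadd45a at 1.77 ± 0.17 and the cell death gene Pmaip1 at -1.35 ± 0.24 (camera adjusted p = 0.0172, and adjusted p = 0.12 with an estimated correlation).

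Several of these calls lay near the threshold and were lost when 1 array was left out. The decidualization list lost its call without EGFR d/d replicate 2 (camera adjusted p = 0.0637) or 3 (0.0613), EGFR f/f replicate 1 (0.0613) or 2 (0.0506), or Wnt4 f/f replicate 1 (0.0878) or 2 (0.0628), with medians of -0.14, -0.15, -0.14, -0.09, -0.09 and -0.17 in that order against -0.16. The kinase inhibitor list lost its call without EGFR f/f replicate 2 (0.0569) or Wnt4 d/d replicate 3 (0.119), with medians of 0.14 and 0.15 against 0.14. In the 12 fits that each left out 1 array, the difference missed limma's adjusted threshold in 9 for Msmo1 and Rrm2, 7 for Smad6, 6 for Bmp2 and 5 for Hsph1, and their highest adjusted p was 0.0867, 0.0782, 0.0702, 0.0762 and 0.0621. That highest value came without Wnt4 f/f replicate 1 for Rrm2 (-0.94) and without EGFR f/f replicate 3 for Msmo1 (-0.8), Smad6 (-1.08), Bmp2 (-1.29) and Hsph1 (-0.6). With a trended, robust variance Bmp2 and Rrm2 missed it as well (limma adjusted p = 0.0563 and 0.0557). In all, 1352 genes differed at a limma adjusted p of 0.05, with 710 positive and 642 negative, a balance that turned under median centring (625 and 683). With the Wnt4 labels exchanged, 8355 genes and 15 lists would differ. As labelled, 13 of the 36 lists did by camera with the preset correlation, 7 up and 6 down, against 0 with an estimated correlation, where the lowest adjusted p was 0.0896. The count of genes was 715 and 600 without EGFR f/f replicates 1 and 3, 808 and 685 without EGFR d/d replicates 1 and 2, 687 and 801 without Wnt4 f/f replicates 1 and 2, and 838, 785 and 2062 without Wnt4 d/d replicates 1, 2 and 3. Interferon response genes had 0 calls among 27 by limma, with a median difference of 0.05 (camera adjusted p = 0.316). With array weights Ifit3 (0.85, limma adjusted p = 0.0452) and Gbp2 (0.56, 0.0439) passed. Without Wnt4 d/d replicate 3 they passed too (1.16, 0.00338, and 0.65, 0.0248), as did Gbp2 with a trended, robust variance (0.53, 0.0492).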

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

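The test used for the stromal share, which replaced a planned one, the tests of RNA degradation, of the glandular pattern and of the Wnt4 transcript, the exchange of labels and the gaps between groups were chosen only after related results had been seen, while the test of Pgr and the splits of the arrays were planned.

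The effects of the knockouts differed for 1352 genes by limma's test of the difference, and with the Wnt4 labels exchanged they would differ for 8355 genes and 15 lists. By list, the median differences of the EGFR effect minus the Wnt4 effect that passed camera were 1.3 for glandular epithelium, 0.42 for smooth muscle, 0.34 for epithelium, 0.28 for pericytes, 0.28 for macrophages and dendritic cells, 0.27 for endothelium and 0.14 for cyclin-dependent kinase inhibitors. They were -0.43 for cholesterol synthesis, -0.28 for G1/S, -0.28 for G2 and mitosis, -0.17 for heat shock, -0.16 for decidualization and -0.15 for BMP and TGF-beta signalling. These calls came with the preset correlation, and 0 of the 36 lists passed with an estimated correlation, where the lowest camera adjusted p was 0.0896. Other splits of the arrays do not exclude chance for these counts. As many genes came in 5 of 100 drawn splits, the real one included, with a highest other count of 5645. In 12 of 100 there were as many lists as the real 13, with a highest other of 16. The 4 other splits with as many genes kept the EGFR arrays as labelled and mixed the Wnt4 arrays, so they held the EGFR effect, a structure of the samples. For the calls within EGFR (7740 genes, 16 lists) and within Wnt4 (4391 genes, 13 lists), the real split was the 1 split of 10 as large. The 10 splits are too few. The highest other counts were 0 genes and 15 lists for EGFR and 0 genes and 12 lists for Wnt4. For genes changed the same way in both knockouts, only the real split, 1 of 100, gave as many as 3550, with a highest other of 0. This count decides nothing, because each of the 99 other drawn splits mixed at least 1 experiment, and a mixed experiment had 0 calls in all 91 splits for EGFR and all 89 for Wnt4.

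Among glandular and epithelial genes, the difference between the effects was 3.99 for Prss28, 3.91 for Prss29, 3.87 for Obp2a, 3.74 for Spink1, 3.49 for Aqp8, 2.76 for Agr2, 2.58 for Prom1, 2.52 for Sox9, 2.01 for Foxa2, 1.82 for Mmp7, 1.62 for Padi1 and 1.31 for Wfdc3. Lower values were -3.57 for Clca1, -3.56 for Ltf, -3.19 for Sprr2f, -2.95 for Krt15, -2.52 for Krt13, -2.1 for Trp63, -1.64 for Krt14, -1.54 for Krt19 and -1.52 for Krt5. In genes of the decidual response and its signals it was -3.2 for Prl8a2, -2.7 for Aoc1, -2.45 for Sfrp5 and -1.92 for Cyp11a1. Further ones were -1.81 for Wnt4, -1.72 for Prl3c1, -1.46 for Egfr, -1.4 for Fosl1, -1.35 for Bmp2, -1.17 for Smad6, -1.1 for Notum and -0.51 for Hbegf. In muscle, vessel and macrophage genes it was 1.19 for Vwf, 0.59 for Tie1, 0.58 for Tek, 0.57 for Csf1r, 0.56 for Actg2, 0.55 for Lmod1, 0.54 for Smtn, 0.45 for Pcp4, 0.45 for Synpo2, 0.4 for Cdh5 and 0.39 for Kcnj8. In metabolic, cell cycle and heat shock genes it was -2.13 for Aass, -0.99 for Rrm2, -0.9 for Msmo1, -0.87 for Hsd17b7, -0.83 for Cdc6, -0.75 for Cyp51, -0.66 for P4ha2, -0.65 for Hsph1 and -0.4 for Hspd1. Elsewhere it was 2.57 for F5, 2.15 for Chodl, 2.11 for Nppa, 2.07 for Prss12, 2.06 for Inmt, 1.77 for Gadd45a and 1.66 for Kit. Smaller positive values were 1.53 for Ier3, 1.01 for Csrnp3, 0.81 for Dbp, 0.72 for Per3, 0.64 for Tac2 and 0.35 for Nr1d2. Negative ones were -2.54 for Serpina1c, -2.29 for Tmem45b, -2.16 for Plekhg4, -1.87 for Serpinb9b, -1.49 for Calb1 and -1.35 for Pmaip1. In the 12 fits without 1 array, limma's call was lost in 11 for Nr1d2, 9 for Rrm2, Msmo1, Tac2 and Dbp, and 8 for Hbegf, Cdh5 and Per3. It was lost in 7 for Smad6, P4ha2, Hspd1 and Pcp4, 6 for Bmp2 and Kcnj8, 5 for Calb1, Fosl1, Hsph1 and Synpo2, and 1 for Cyp11a1. The highest adjusted p came without EGFR f/f replicate 3 for each of these except Rrm2 and Dbp (Wnt4 f/f replicate 1), Tac2 (EGFR f/f replicate 1) and Cdh5 (EGFR d/d replicate 2). It reached 0.123 for Nr1d2, with a value of 0.32. In the mean of all probe sets the difference missed the threshold for Csrnp3 (0.34, adjusted p = 0.0921), Per3 (0.2, 0.339), Nr1d2 (0.19, 0.319), Cdh5 (0.29, 0.0928), Hsd17b7 (-0.46, 0.0996) and Synpo2 (-0.04, 0.903). With plain probe sets alone it did for Msmo1 (-0.22, 0.478), Hsd17b7 (-0.56, 0.106) and Nr1d2 (0.35, 0.058). With a trended, robust variance it did for Bmp2 (0.0563) and Rrm2 (0.0557), and with median centring for Nr1d2 (0.0539).

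The controls of the experiments differed as well. For 598 of the 1352 genes, and for 23 of the 72 named here, the gap between Wnt4 f/f and EGFR f/f was larger than the gap between the d/d groups. Wnt4 f/f minus EGFR f/f was -2.25 for Prl8a2, -1.97 for Sfrp5, -1.66 for Wnt4, -1.64 for Aass, -1.48 for Prl3c1 and -1.41 for Cyp11a1, where the d/d groups lay 0.95, 0.48, 0.15, 0.49, 0.24 and 0.51 apart. For each of these genes most of the difference thus lay between controls.

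Probe sets with no gene listed carried signal outside the main comparisons, with 1177 of 9160 (12.8%) past limma's adjusted threshold in EGFR d/d and 593 (6.5%) in the arrays labelled Wnt4 d/d.

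The first pattern weighed was the set of genes that changed the same way in both knockouts. For RNA degradation, the 3′ minus 5′ difference of the Gapdh and actin controls moved by at most 0.07. This was under 50% of the median change of the shared genes. The group means of these probe sets, from 12.79 to 14.46, lay near the highest array value of 14.7, where a shift may be hard to see. The difference of 18S RNA, which has no poly(A) tail, moved by -0.45 in EGFR d/d and -0.02 in Wnt4 d/d. The Gapdh and actin values thus argue against degradation only as far as such bright probe sets can show it. A lower share of stromal cells as the whole cause stays open. The lower bound of the epithelial median lay at least 0.12 above the upper bound of the endothelial one in each knockout. That pair was picked after the intervals were seen, and the planned criterion, intervals on opposite sides of 0, was not met. The epithelial interval also overlapped the pericyte one, with 0.79 to 1.25 against 0.43 to 0.85 in EGFR d/d. In Wnt4 d/d they were 0.37 to 0.9 and 0.16 to 0.58. Stromal fibroblast markers, which a lower share would lower, had a median of 0.21 (0.07 to 0.55) in EGFR d/d. In Wnt4 d/d it was 0.09 (-0.03 to 0.29). Of these 14 markers, 7 rose and 2 fell in EGFR d/d, and 5 rose and 2 fell in Wnt4 d/d. As a set they thus gave no sign of a lower share. These intervals came from resampling genes, not pools, so they cannot decide this. Lower Pgr dosage from the Cre allele stays open although the lower 95% bound of the Pgr change, -0.2, met the planned criterion against it, because that rested on 1 probe set while another fell by 0.51 and 0.91 and a further one rose by 0.72 and 0.56. A shared dependence of decidualization on EGFR and Wnt4 stays open as a hypothesis, which rests on the Wnt4 labels, since with these exchanged 109 genes would change the same way and 3550 opposite ways.

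The second pattern was that glandular markers moved apart in the knockouts. Uneven sampling of glands between pools stays open, because the gap of 0.62 between the lowest Wnt4 f/f and the highest Wnt4 d/d array, first read against it beside an SD within groups of 0.16, follows from the fall of the markers itself. A different level in the control groups was argued against by a median of 0.28 between Wnt4 f/f and EGFR f/f, beside a median difference of effects of 1.3. A different dependence of glands on EGFR and Wnt4 is a hypothesis that the design names, and it rests on the Wnt4 labels, with which exchanged the median difference would be -0.22 (camera adjusted p = 0.516).

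The third pattern was the Wnt4 transcript, which was not lower in the arrays labelled Wnt4 d/d. An exchange of the labels, which would give a change of -0.12, stays open. The dimmer Pgr probe sets changed by -0.51 and 0.72 in EGFR d/d and, as labelled, by -0.91 and 0.56 in Wnt4 d/d. Exchanged labels would turn the latter pair. This speaks against an exchange only if these changes come from the Cre allele, which was not tested. The brightest Pgr probe set hardly changed (-0.01 and -0.07). A turned Wnt4 change that missed the threshold was the first criterion against an exchange and was met (limma adjusted p = 0.534). That criterion was replaced afterwards because Wnt4 f/f already lay within 0.08 of EGFR d/d, where a fall may not be visible. Probe sets outside the deleted part, with a lower change of 0.12 of the pair, and a signal at background in the controls stay open in the same way, since neither the floxed exons nor the background of these probe sets is known. No biological explanation was tested.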

How the results depend on the processing

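Each alternative here was planned. The counts of calls in EGFR d/d and in the arrays labelled Wnt4 d/d, the shared genes, the correlation and the numbers of shifted lists stayed within 1.5 times (r within 0.1) of the reported values under each normalization, the filter on dim genes, the array weights, separate fits and both other choices of probe sets, where these were run. The count of differing effects rose to 2053 with a trended, robust variance, and the cause was not tested. The balance of rises and falls was less stable. More fell than rose under median centring in EGFR d/d (3737 higher, 3951 lower), and in the mean of all probe sets in Wnt4 d/d (1915 and 1985). For the difference, more were negative under median centring (625 positive, 683 negative), without dim genes (937 and 944), with a trended, robust variance (999 and 1054), with array weights (1001 and 1003) and without EGFR d/d replicate 3 (689 and 801). A fold of at least 1.5 left 2307 genes for EGFR, 859 for Wnt4, 558 for the difference and 594 shared, by its own construction. With an estimated correlation, 0 lists shifted for EGFR, 0 for Wnt4 and 0 for the difference. Leaving out each array in turn gave 6720 to 7875 genes for EGFR, 2996 to 4654 for Wnt4, 600 to 2062 for the difference and 2418 to 3850 shared, an r of 0.6 to 0.7, and 14 to 17, 11 to 15 and 12 to 16 lists. Changes of direction came with the choice of probe sets. In the mean of all probe sets, Synpo2 was -0.3 in EGFR d/d, -0.27 in Wnt4 d/d and -0.04 in the difference. With plain probe sets alone, Ighm was -0.12 and Ccdc39 -0.08 in EGFR d/d, and Pnpla2 was -0.17 and Ccdc39 -0.04 in Wnt4 d/d, none past the threshold. Over all other values of single lists, 1919 kept direction and side of the threshold, 88 were weaker, 36 stronger and 0 reversed, and over those of single genes 10229 kept them, 474 were weaker and 94 stronger. Floors of 1 and 32 were not run because the values are already log2. No paired analysis was possible because replicate numbers here only name the arrays. No background or detection values were given, so which genes lie near background is not known.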

Other observations

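The gene families in the first paragraphs, the comparison of the control groups and the control probe sets were chosen after values had been seen, while the tests of genes near the loci were planned.

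Basal and squamous epithelial genes rose in the arrays labelled Wnt4 d/d. Of 15 such genes, 9 rose and 1 fell, with a median log2 fold change of 0.55. Trp63, the transcription factor of basal epithelial cells, rose by 2.15 ± 0.15, and the stratified epithelial keratins Krt13, Krt14 and Krt5 rose by 2.65 ± 0.2, 2.08 ± 0.19 and 1.59 ± 0.14 (limma adjusted p at most 2.69e-05). In EGFR d/d the same genes had changes of 0.05, 0.13, 0.44 and 0.07, none past the threshold except Krt14 in separate fits (adjusted p = 0.04) and without Wnt4 d/d replicate 2 (0.0208), and the difference between the effects passed it for each, at -2.1, -2.52, -1.64 and -1.52. Of all 15 genes, 3 rose and 1 fell in EGFR d/d, the rises including Itgb4 (0.82 ± 0.06) and Col17a1 (0.37 ± 0.1). The family was put together from genes seen to rise, so no test of it as a set is given. Kit, the stem cell factor receptor, went opposite ways, with 0.35 ± 0.07 in EGFR d/d and -1.31 ± 0.07 in the arrays labelled Wnt4 d/d. These directions rest on the Wnt4 labels, since Wnt4 was not lower there.

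Genes of the circadian clock changed, and most genes of ribosome biogenesis fell, in both knockouts. Of 16 clock genes, 9 and 8 rose and 3 and 1 fell, the rises led by Dbp (2.42 and 1.62), Per3 (1.69 and 0.97), Nr1d2 (1.04 and 0.69) and Tef (0.95 and 0.56). In the mean of all probe sets Tef was 0.12 in the arrays labelled Wnt4 d/d (limma adjusted p = 0.325). Nfil3, a clock repressor, fell by 0.37 and 0.54. Of 44 ribosome biogenesis genes, 36 and 25 fell and 1 and 0 rose. Of 75 mitochondrial ribosome genes, 60 and 38 fell and 2 and 0 rose. Of 39 proteasome genes, 31 and 11 fell and 3 and 1 rose, and of 16 tRNA synthetase genes, 14 and 7 fell and 1 and 1 rose. Of 47 cytosolic ribosome genes, 3 and 0 fell and 2 and 1 rose. Families were gathered by symbol, and 14 genes that only share a prefix were left out after values had been seen. No test of these families as sets is given, since they were picked after values had been seen. Of 33 Hox genes, 17 and 11 rose and 1 and 1 fell, and of 20 semaphorins, 12 and 8 rose and 1 and 0 fell. Of 19 glutathione transferases, 10 and 7 rose and 0 fell in either. Of 20 claudins, 9 and 8 rose and 0 and 1 fell, and of 44 keratins, 7 and 8 rose and 2 and 3 fell, while 0 of 10 granzymes passed limma's threshold in either comparison. Beside these counts, 4200 and 2426 of all 18194 genes rose and 3540 and 1965 fell, so some calls come in any family. In all, 13 families were looked at, each listed here. The time of day at which tissue was collected is not given in the sources used here.

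The control groups differed from each other. By limma, 4950 genes differed between Wnt4 f/f and EGFR f/f at an adjusted p of 0.05. Wnt4 was lower in Wnt4 f/f by a log2 difference of -1.66 ± 0.12, Prl8a2 by -2.25 ± 0.41 and Prl3c1 by -1.48 ± 0.24. The experiment and the mouse line cannot be separated in this contrast. The hybridisation control BioB had a mean log2 signal of 8.74 in EGFR f/f and 6.88 in Wnt4 f/f on its 3′ probe set, with SDs of 0.04 on both. It was 8.95 in EGFR d/d (SD 0.05) and 6.85 in Wnt4 d/d (SD 0.14). The 5′ and middle BioB probe sets were also higher in EGFR d/d than in EGFR f/f, at 8.8 against 8.65 and 9.51 against 9.24. In Wnt4 d/d against Wnt4 f/f they were 6.69 against 6.67 and 7.26 against 7.26. Whether this difference between the EGFR groups adds to the calls in EGFR d/d was not tested. The means of the 18S ribosomal RNA probe sets were lower in both knockouts. From EGFR f/f to EGFR d/d they went from 14.14 to 14.04 at the 5′ end, from 13.16 to 12.89 in the middle and from 11.71 to 11.16 at the 3′ end, and from Wnt4 f/f to Wnt4 d/d from 13.46 to 12.5, 12.51 to 11.14 and 11.6 to 10.63, with an SD of up to 0.44.

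Genes beside the loci did not change more often than others, which tested whether DNA carried along with an allele could account for calls. Of 82 genes on the array nearest to Pgr, 16 (19.5%) changed the same way in both knockouts, as did 19.5% of other genes (Fisher's exact p = 1, two-sided). Of 100 genes nearest to Egfr, 43 (43%) changed in EGFR d/d against 42.6% of other genes (Fisher's exact p = 1), and of 100 nearest to Wnt4, 21 (21%) changed in the arrays labelled Wnt4 d/d against 24.2% (Fisher's exact p = 0.558). Neighbouring genes are not independent, and effects of carried DNA on a few of them stay open.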
